A study of Homo sapiens with 8 samples.

How the data were processed

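RNA from 4 human ovarian cancer cell lines, each with and without pI:pC, was measured on 8 Affymetrix arrays of 22277 probe sets. Per the labels' protocols, cells were grown in medium with fetal bovine serum, total RNA was taken up in Trizol and biotin-labelled cRNA was hybridised. pI:pC was added at several concentrations, and the labels do not say which array had which. The values are log2 expression levels that the authors deposited, made with RMA per the submitters' processing notes. By its usual definition RMA corrects background, brings the arrays to 1 distribution and summarises the probes of a probe set. Its version, the software that ran it and whether all arrays were processed together are not given in the sources used here. The deposited log2 columns had medians between 6.19 and 6.30 and were not exactly identical in distribution. RMA compresses differences of dim probe sets, so the change of a gene near background is understated, and the background signal is not given.

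Probe sets were named from the platform annotation supplied with the data. Of the probe sets, 19064 carry 1 gene symbol, 1043 several, and 2170 are not named here (62 of all are array controls). No symbol needed an update through its gene identifier, and 12 probe sets had an identifier not found in the gene table used. For each of the 11963 genes the probe set with the highest mean over the 8 arrays was used, and 4310 genes have more than 1. Among the 120 genes the rule below names, 52 have more than 1 probe set, and 11 have another probe set with the opposite sign of mean change. No gene coordinates are given.

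Groups and cell lines came from the sample labels. The cell line pairs the treated with the untreated array. Arrays of 1 line correlated at 0.992 to 0.997 and arrays of different lines at 0.898 to 0.947, and the deviations from the group means correlated within every pair (0.945 to 0.968). The main test was limma (version 3.58.1, R version 4.3.3), lmFit and eBayes, on the log2 values with the cell line as a block. It has 3 residual degrees of freedom and 4.41 prior degrees of freedom, and was two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A mean change is treated minus untreated, averaged over the lines, with the SD over the 4 lines. The labels give 1 treated and 1 untreated array per line and do not say whether an array held a single culture or a pool. The p-values of single genes therefore measure the spread between lines, and no technical or culture error within a line is known.

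The 22 gene lists hold 486 members, of which 415 were measured. They cover interferon-stimulated genes, double-stranded RNA sensing, interferon genes, cytokines, NF-kB targets, MHC class I and II, death receptors and caspases, pro-apoptotic BCL2 members, apoptosis inhibitors, stress responses, p53 targets, G2/M, S phase, cholesterol synthesis, drug efflux, epithelial, mesenchymal, leukocyte and endothelial markers, reference genes and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the list genes with all other genes under that assumed correlation, so its p-values are no measure of agreement between the lines. The correlation estimated from the data was 0.752 for interferon-stimulated, 0.675 for MHC class I and 0.853 for G2/M genes. Members were also adjusted over their list alone, with no correction for the number of lists. No camera call held with an estimated correlation, and none of the lists passed fry, limma's rotation test, for a shift in 1 direction or in either. Within lines there was no test. A gene was counted when treated minus untreated was at least 1 in size on the log2 scale and the higher value was at or above the median gene of that array pair. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Expected overlaps are products of the 2 counts divided by the genes that could be counted.

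Lists, tests, thresholds and alternatives were fixed before the data were examined, as was the rule for naming genes. Where fewer than 5 genes pass in a direction, the rule takes the 10 with the smallest p and the same sign in all 4 lines. It adds the 4 members of each list with the largest mean change in size, a set of sensor, cytokine and apoptosis genes fixed by name, and the 5 largest differences each way among the genes counted in a line. Other genes in the text were chosen after their values were seen, except the MHC class I, cytokine and pro-apoptotic genes that passed over their list alone and the genes shared by CAOV-3 and OVCAR-3, which are named in full. The interferon-stimulated genes that passed over their list alone are given as a count. Alternatives were the fit without the block, a filter at the median level, the mean or the most variable of a gene's probe sets, quantile normalization again, centring on the median, eBayes with trend and robust, other thresholds, and leaving out each line.

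The test was run on simulated data of the same 11963 genes with 200 changed. It recovered 94.5% of genes changed by 0.5 on the log2 scale with 7 false calls, 99.5% at 1 with 23 and 100% at 2 with 10. These simulated changes were equal in every line. The noise was drawn independently for each gene, with variances already shrunk toward a common value. The recovered shares therefore do not carry over to genes that are correlated or that change unequally between lines. Probe sets with several genes or no name were left out of tests by gene. Figures were drawn with matplotlib (version 3.10.9) in Python (version 3.11.15).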

Results

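Expression was measured on 8 Affymetrix arrays in 4 established human ovarian cancer cell lines, SKOV-3, DOV-13, CAOV-3 and OVCAR-3. For each line 1 array held RNA from cells given pI:pC and 1 array held RNA from untreated cells, so each group had 4 arrays. pI:pC (polyriboinosinic:polyribocytidylic acid) is a synthetic double-stranded RNA that cells sense as they would viral RNA. The series title names the induction of apoptosis by double-stranded RNA and a greater potency of chemotherapy as its subject. The labels give neither the dose nor the exposure time of an array. The median deposited log2 value lay between 6.19 and 6.30 on all 8 arrays, and the number of arrays limits the precision of every comparison. The question asked of the data was which genes differed between treated and untreated cells over the 4 lines, and what each line showed.

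Genes induced by interferon were higher after pI:pC, mostly in CAOV-3 and OVCAR-3. All 43 measured interferon-stimulated genes had a positive mean change over the 4 lines, with a median of 0.749 on the log2 scale, and 19 were higher in every line. IFI44L had a mean log2 change of 2.07 ± 2.69 (SD, n = 4 lines), IFIT1, which binds viral RNA, 1.88 ± 1.88, IFI44 1.74 ± 1.22, and the antiviral GTPase MX1 1.59 ± 1.78. The ubiquitin-like modifier ISG15 had 1.57 ± 1.42, LAMP3 1.54 ± 1.38 and the transcription factor IRF7 0.60 ± 0.73. Without OVCAR-3 the means were 0.925 for IFI44L, 1.107 for IFIT1, 0.812 for MX1, 1.025 for ISG15 and 0.373 for IRF7. The median difference of the list was 1.65 in CAOV-3 and 1.29 in OVCAR-3, against 0.12 in SKOV-3 and 0.06 in DOV-13. In CAOV-3 and OVCAR-3 it lay above all 10000 random lists of matched level. The list was shifted upward by limma's camera test with a preset correlation (adjusted p = 2.06e-30), but not with one estimated from the data (adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone, 24 of the 43 genes passed, and 0 passed over all genes tested. That adjustment has no correction for the number of lists. The smallest adjusted p of the 24 was 0.0463, so all of them lay between that value and the threshold of 0.05. The 24 fell to 0 without CAOV-3 (smallest adjusted p = 0.143), to 0 without OVCAR-3 (smallest adjusted p = 0.058) and to 0 without the cell line as a block (smallest adjusted p = 0.616).

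**Figure D1:**
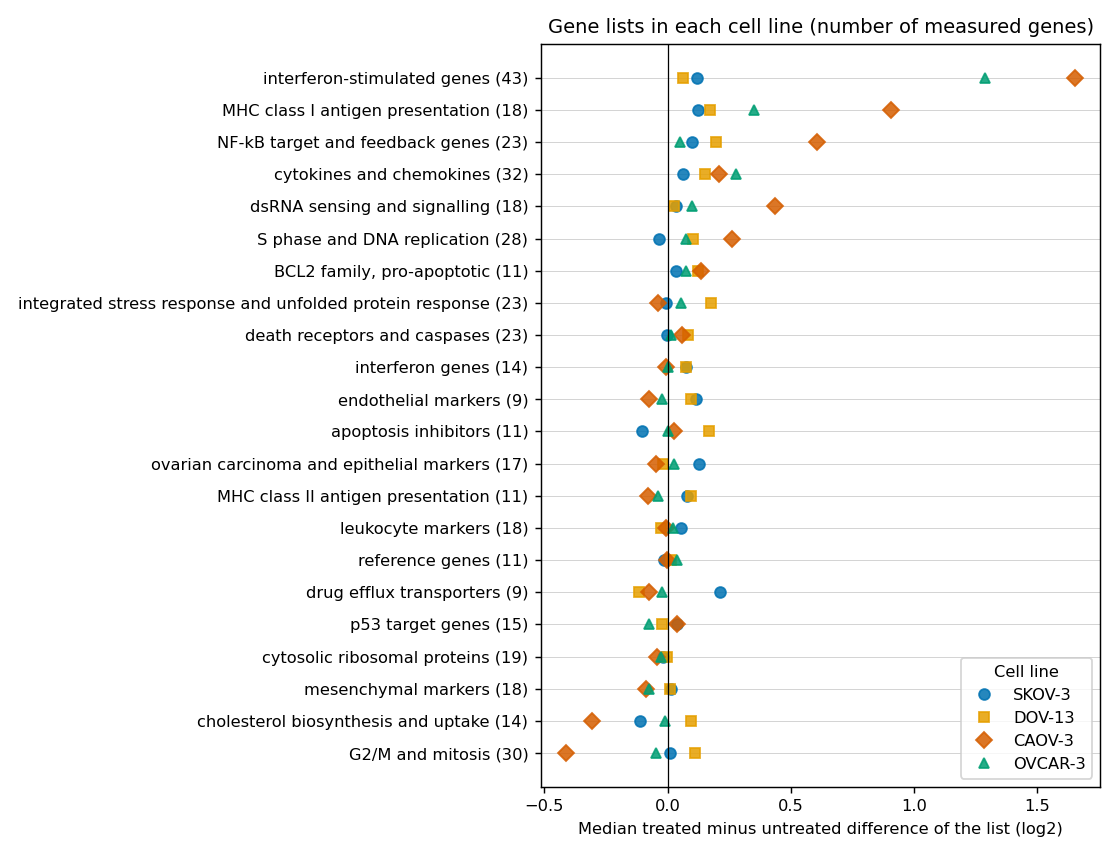
Median treated minus untreated log2 difference (horizontal axis) of 22 gene lists (vertical axis, with the number of measured genes) in each cell line, 1 array per condition, with 1 symbol per line. Interferon-stimulated genes stood at 1.65 in CAOV-3 and 1.29 in OVCAR-3, and at 0.12 or less in SKOV-3 and DOV-13, while G2/M genes were at -0.41 in CAOV-3.

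Of 32 measured cytokine and chemokine genes, 27 had a positive mean change and 9 were higher in every line. CXCL2, which encodes an attractant of neutrophils, had a mean log2 change of 0.88 ± 0.49 (SD, n = 4 lines). CXCL8 (interleukin 8) had 1.46 ± 1.45, the interferon-induced T cell attractants CXCL11 and CXCL10 had 1.70 ± 2.97 and 1.34 ± 1.79, IL6 0.77 ± 1.23 and CCL5 0.33 ± 0.57. Without CAOV-3 the means were 0.80 for CXCL8, 0.22 for CXCL11, 0.50 for CXCL10, 0.16 for IL6 and 0.046 for CCL5. The list was shifted upward by camera (adjusted p = 5.33e-09), but not with an estimated correlation (adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone only CXCL2 passed (adjusted p = 0.0281), and 0 genes passed over all genes. No member passed without DOV-13, CAOV-3 or OVCAR-3, or without the cell line as a block (smallest adjusted p = 0.145, 0.109, 0.176 and 0.789), and 5 passed without SKOV-3.

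Targets and feedback inhibitors of NF-kB, the transcription factor of inflammatory signalling, were higher in 22 of 23 measured cases. TNFAIP3, which ends NF-kB signalling, had a mean log2 change of 0.57 ± 0.77 (SD, n = 4 lines), the protease gene PLAU 0.55 ± 0.43, the adhesion molecule gene ICAM1 0.55 ± 0.87, TNIP1 0.53 ± 0.72 and the inhibitor gene NFKBIA 0.51 ± 0.44. Without CAOV-3 the means were 0.19 for TNFAIP3, 0.13 for ICAM1, 0.18 for TNIP1, 0.38 for PLAU and 0.31 for NFKBIA. The list median was 0.61 in CAOV-3, 0.20 in DOV-13, 0.10 in SKOV-3 and 0.05 in OVCAR-3. Camera called the list upward (adjusted p = 1.25e-08), and the call was lost with an estimated correlation (adjusted p = 0.498 with an estimated correlation). No member passed, adjusted over the list alone or over all genes.

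All 18 measured genes of antigen presentation by MHC class I had a positive mean change, and 9 were higher in every line. The immunoproteasome subunit genes PSMB9 and PSMB10 had mean log2 changes of 0.67 ± 0.41 and 0.53 ± 0.53 (SD, n = 4 lines), the peptide transporter gene TAP1 0.62 ± 0.80, HLA-F 0.50 ± 0.39 and HLA-C 0.36 ± 0.16. Without CAOV-3 the means were 0.488 for PSMB9, 0.306 for PSMB10, 0.276 for TAP1, 0.302 for HLA-F and 0.332 for HLA-C. The list median was 0.91 in CAOV-3, 0.35 in OVCAR-3, 0.17 in DOV-13 and 0.12 in SKOV-3. The list was shifted upward by camera (adjusted p = 4.93e-17), but not with an estimated correlation (adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone, 10 of the 18 passed, HLA-B, HLA-C, HLA-F, HLA-G, TAPBP, PSMB8, PSMB9, PSMB10, PSME1 and PDIA3, and 0 over all genes. HLA class I genes are close copies, so their probe sets can take up each other's transcripts. The count was 5 without CAOV-3, and 0 without OVCAR-3 (smallest adjusted p = 0.0561) or without the cell line as a block (smallest adjusted p = 0.72).

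The cytosolic sensors of double-stranded RNA were among the higher genes, and the measured interferon genes had changes near 0. IFIH1 (MDA5) had a mean log2 change of 1.31 ± 1.35 (SD, n = 4 lines), RIGI 0.67 ± 0.85, the kinase gene EIF2AK2 (PKR) 0.42 ± 0.53, DHX58 0.27 ± 0.30 and the endosomal receptor gene TLR3 0.25 ± 0.52. Without CAOV-3 the means of TLR3 and RIGI were -0.004 and 0.33, and without OVCAR-3 that of EIF2AK2 was 0.184. Of 18 measured sensing and signalling genes 14 had a positive mean change. Camera called the list upward (adjusted p = 0.00138), but not with an estimated correlation (adjusted p = 0.498 with an estimated correlation) and not without CAOV-3 (adjusted p = 0.201). It was also lost when only genes above the median level were tested (adjusted p = 0.148). The 14 measured interferon genes had a median mean change of 0.012 and were not called (adjusted p = 0.321). IFNB1 had -0.04 ± 0.12, IFNA4 0.11 ± 0.10, IFNW1 0.11 ± 0.11, IFNA10 0.11 ± 0.11 and IFNA17 0.11 ± 0.22. IFNB1 was at a log2 level between 4.34 and 4.68 on all 8 arrays, under the median of each. The median level of the interferon list lay between 4.22 and 4.41 in every line, with and without pI:pC. IFNL1, IFNL2 and IFNL3 were not measured. Changes near 0 at such levels do not show that interferon genes were not induced. No member of either list passed, adjusted over the list alone or over all genes.

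The lists of cell death genes had small median changes. The 23 measured death receptor and caspase genes had a median mean change of 0.051 and were not called by camera (adjusted p = 0.284). FAS had a mean log2 change of 0.36 ± 0.35 (SD, n = 4 lines), the TRAIL receptor gene TNFRSF10B 0.23 ± 0.32, the TRAIL decoy receptor gene TNFRSF10D -0.28 ± 0.14 and CASP2 0.20 ± 0.29. TNFSF10, which encodes TRAIL, had 0.20 ± 0.32 and CASP8 0.13 ± 0.19. Without CAOV-3 the means were 0.18 for FAS, 0.068 for TNFRSF10B, 0.086 for CASP2 and 0.055 for CASP8. Without OVCAR-3 TNFSF10 had 0.052. The pro-apoptotic BCL2 family had a median of 0.081 over 11 genes, and its camera adjusted p was 0.051. It was called upward without SKOV-3 (adjusted p = 0.0167), with the level filter (0.00901), the mean of all probe sets (0.0136) and quantile normalization (0.048), but not with an estimated correlation (adjusted p = 0.498 with an estimated correlation). In this family BIK had 0.31 ± 0.17 and was the only gene that passed adjusted over the list alone (adjusted p = 0.0476), with 0 over all genes. The adjustment over the list alone has no correction for the number of lists. BIK did not pass without DOV-13, CAOV-3 or OVCAR-3 (smallest adjusted p in the list 0.0832, 0.174 and 0.225), or without the cell line as a block (0.979). PMAIP1 (NOXA) had 0.14 ± 0.16 (0.057 without OVCAR-3), BNIP3 0.18 ± 0.56 (-0.087 without CAOV-3), BID 0.15 ± 0.32 (0.014 without CAOV-3) and BAX -0.20 ± 0.24. Another probe set of BAX went the opposite way. The 11 apoptosis inhibitors had a median of 0.057 (adjusted p = 0.531), with BIRC5 (survivin) at -0.15 ± 0.30, BCL2L1 at 0.14 ± 0.10, BCL2 at -0.12 ± 0.17 and BIRC2 at 0.11 ± 0.32. For BCL2L1 and BCL2 the sign turned when all probe sets of the gene were averaged, to -0.003 and 0.001. Without CAOV-3 the sign turned for BIRC5 (0.001) and BIRC2 (-0.046). Adjusted over the list alone or over all genes, 0 death receptor, caspase and inhibitor genes passed.

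The stress and drug transport lists were not called either. The integrated stress and unfolded protein responses had a median mean change of 0.065 over 23 genes (adjusted p = 0.147), with the chaperone genes PDIA4 at 0.23 ± 0.39 (SD, n = 4 lines) and HYOU1 at 0.21 ± 0.25. DDIT4 had -0.18 ± 0.32 and SLC7A11 -0.17 ± 0.38, which became 0.003 without CAOV-3. The 15 p53 target genes had a median of -0.025 and a mean of 0.003, opposite in sign, and the test pointed downward (adjusted p = 0.531). In that list ZMAT3 had -0.24 ± 0.26. The 9 drug efflux transporter genes had a median of -0.016 (adjusted p = 0.322), with ABCC3 at -0.21 ± 0.37, ABCC4 at -0.08 ± 0.06, ABCC5 at -0.07 ± 0.14 and MVP at 0.12 ± 0.16. No member of these lists passed, adjusted over the list alone or over all genes.

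Genes of the cell cycle and of cholesterol synthesis were shifted by camera, and CAOV-3 carried these calls. Of 30 measured G2/M and mitosis genes 27 had a negative mean change, among them KIF20A at -0.24 ± 0.43 (SD, n = 4 lines), DLGAP5 at -0.23 ± 0.44, CCNB2 at -0.20 ± 0.33 and CDC25C at -0.20 ± 0.15. In CAOV-3 all 30 were lower in the treated array, with a median of -0.41. The downward call (adjusted p = 4.82e-06) was lost with an estimated correlation (adjusted p = 0.52 with an estimated correlation), and without CAOV-3 the list pointed upward (adjusted p = 0.836). S phase genes went the other way, with 26 of 28 positive, including FEN1 at 0.17 ± 0.21, the cyclin genes CCNE1 at 0.16 ± 0.33 and CCNE2 at 0.15 ± 0.33, and CDT1 at 0.14 ± 0.07. The upward call of this list (adjusted p = 2.29e-05) was lost with an estimated correlation (adjusted p = 0.498 with an estimated correlation) and without CAOV-3 (adjusted p = 0.201). Of 14 cholesterol synthesis and uptake genes 12 had a negative mean change, led by INSIG1 at -0.35 ± 0.66 (-0.037 without CAOV-3), HMGCS1 at -0.26 ± 0.58 (0.022 without CAOV-3), DHCR7 at -0.25 ± 0.37 (-0.142 without CAOV-3) and MSMO1 at -0.23 ± 0.34 (-0.064 without CAOV-3). Their downward call (adjusted p = 0.00104) was lost with an estimated correlation (adjusted p = 0.498 with an estimated correlation) and without CAOV-3 (adjusted p = 0.396). No member of these 3 lists passed, adjusted over the list alone or over all genes.

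Markers of cell identity and reference genes had median mean changes between -0.023 and 0.066. Class II antigen presentation (11 genes, median 0.066, adjusted p = 0.22, and called upward without the cell line as a block at 0.0452) was led by the lysosomal protease gene CTSS at 0.54 ± 0.71 (SD, n = 4 lines) and CD74 at 0.41 ± 0.73. HLA-DMA had -0.28 ± 0.28 and HLA-DRA 0.16 ± 0.19. Ovarian carcinoma and epithelial markers had a median of 0.055 (17 genes, adjusted p = 0.42), with MUC16, which encodes CA125, at 0.24 ± 0.28, MUC1 at 0.17 ± 0.19, EPCAM at 0.16 ± 0.27 and CLDN4 at 0.15 ± 0.30. MUC16 was dim in untreated SKOV-3 (4.13), DOV-13 (4.05) and CAOV-3 (4.80). In OVCAR-3, where its untreated level was 9.59, it differed by -0.067. Mesenchymal markers had -0.016 (18 genes, adjusted p = 0.186), with SNAI2 at -0.34 ± 0.51, ACTA2 at 0.22 ± 0.43, ZEB1 at -0.17 ± 0.11 and TGFBI at -0.15 ± 0.56. Leukocyte markers had 0.032 (18 genes, adjusted p = 0.531), with CD14 at -0.33 ± 0.40, and endothelial markers had 0.063 (9 genes, adjusted p = 0.0834, and called upward without the block at 0.00561 and without CAOV-3 at 0.0277), with ROBO4 at 0.23 ± 0.21. With an estimated correlation neither the endothelial list (adjusted p = 0.498 with an estimated correlation) nor the class II list (adjusted p = 0.52 with an estimated correlation) was called. Cytosolic ribosomal protein genes had -0.023 (19 genes, adjusted p = 0.0834) and the reference genes 0.006 (11 genes, adjusted p = 0.531). Within the latter B2M, which is also the MHC class I light chain, had 0.18 ± 0.20. No member of these lists passed, adjusted over the list alone or over all genes.

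Gene by gene, the treated and untreated arrays did not separate over the 4 lines. In limma's test with the cell line as a block, 0 of 11963 genes were raised and 0 lowered at an adjusted p under 0.05, and the smallest adjusted p was 0.988. At an unadjusted p under 0.05 there were 448 genes, 291 higher and 157 lower, where 598 are expected by chance. The same sign in all 4 lines was seen for 1364 genes (11.4%), and chance gives 12.5%. For IFI44L, MX1 and IRF7 the SD over the lines exceeded the mean change.

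The genes closest to the threshold with 1 sign in all lines did not pass (adjusted p = 0.988 for each). On the higher side, besides CXCL2, HLA-C, PSMB9 and IFI44, these were LCN2 (lipocalin 2, an iron-withholding defence protein) at 0.54 ± 0.28 (SD, n = 4 lines), the cytokine receptor gene IL27RA at 0.39 ± 0.21, CD70 at 0.31 ± 0.12, IDO1, which degrades tryptophan, at 0.27 ± 0.09, ANGPTL4 at 0.26 ± 0.08 and GRINA at 0.24 ± 0.05. On the lower side, besides TNFRSF10D, they were DCLK1 at -0.49 ± 0.23, NAP1L3 at -0.49 ± 0.34, SEMA5A at -0.25 ± 0.09, MAGEH1 at -0.45 ± 0.32, TAF9B at -0.53 ± 0.40, MEST at -0.24 ± 0.09, PPIP5K1 at -0.25 ± 0.13, KIF16B at -0.31 ± 0.21 and the apoptosis repressor gene NOL3 at -0.20 ± 0.04. The levels of IDO1, ANGPTL4, TNFRSF10D, SEMA5A and KIF16B lay under the median gene of the array pair in every line, with and without pI:pC.

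By line, CAOV-3 showed the most differences. With 1 array per condition no line has a replicate check or a test, and the values describe these array pairs. A gene was counted where the arrays differed by 1 or more on the log2 scale and the higher value reached the median gene. In CAOV-3, 101 genes were counted as higher and 16 as lower. Of the 101, 30 were interferon-stimulated genes (0.69 expected from their share of the genes), 8 NF-kB targets (0.279 expected), 7 cytokines or chemokines (0.148 expected) and 7 MHC class I genes (0.279 expected), and 45 belonged to no list. CXCL11 went from a log2 level of 3.66, near the lowest values of the array, to 9.79, and CXCL10 from 5.09 to 8.95. CXCL8 was higher by 3.45, LAMP3 by 2.99, IFI44L by 2.89, IL6 by 2.60, ICAM1 by 1.80, TNFAIP3 by 1.69, RIGI by 1.70 and CCL5 by 1.18, and TLR3 went from 6.67 to 7.68. CCL5 reached 5.81, under the median gene of this pair (6.758), and was not among the 101. FAS was higher by 0.88, and TNFSF10 differed by -0.002. The largest negative differences were those of ID4, a repressor of helix-loop-helix transcription factors, at -2.11, IGFBP5 at -2.08, ACO1 at -1.57, and AGR2 and DLX2 at -1.51 each. In the mean over lines 1 of the 4 other probe sets of IGFBP5, and the 1 other of DLX2, had the opposite sign. Without CAOV-3 the mean of IGFBP5 turned from -0.32 to 0.267 and that of AGR2 from -0.358 to 0.027.

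In OVCAR-3, 26 genes were counted as higher and 0 as lower, and all 26 belonged to the fixed lists. Of these, 22 were interferon-stimulated genes, where 0.136 are expected. IFI44L went from a log2 level of 4.23 to 9.74, IFIT1 from 5.19 to 9.40, MX1 from 6.33 to 10.26 and ISG15 from 8.01 to 11.21. IFI44 was higher by 3.32, and IFIH1 by 2.46 in both OVCAR-3 and CAOV-3. CXCL8 was higher by 1.28 and CXCL10 by 1.36, while CXCL11 was higher by 0.49 and IL6 by 0.37. CXCL10 reached 6.58, under the median gene of this pair (6.658), and was not among the 26. No member of the NF-kB list reached a difference of 1, with TNFAIP3 at 0.19 and ICAM1 at 0.12. That list does not hold CXCL8 and CXCL2 (higher by 1.23), which were among the 26 and stand in the cytokine list. TNFSF10 was higher by 0.63.

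**Figure D2:**
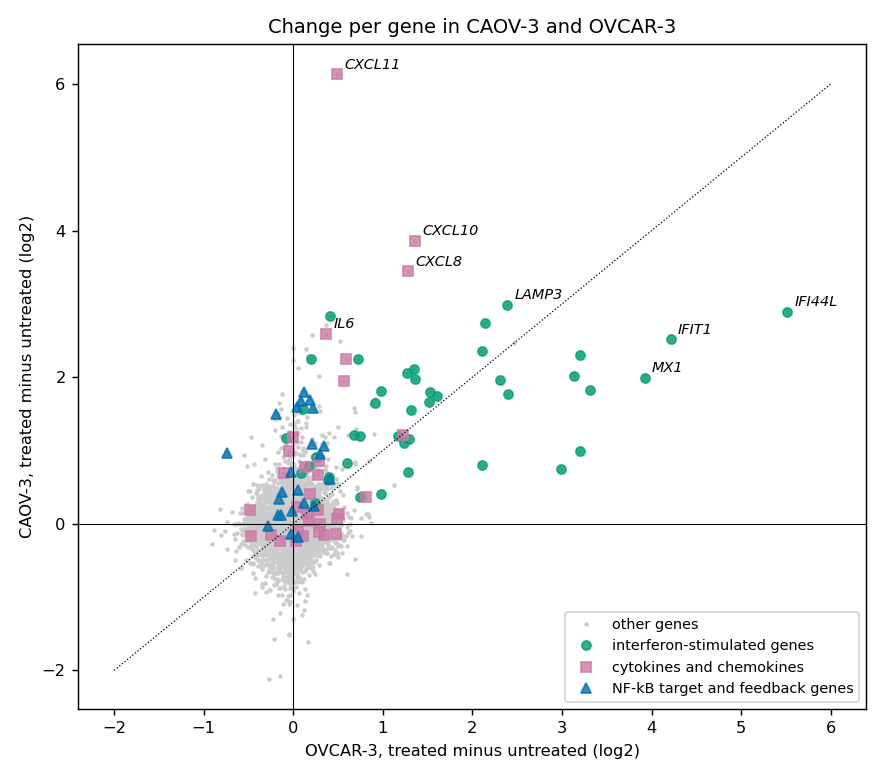
Treated minus untreated log2 difference of each gene in OVCAR-3 (horizontal axis) and CAOV-3 (vertical axis), 1 array per condition, with 3 gene lists marked and the dotted line at equal values. Of the 43 interferon-stimulated genes 42 were higher in OVCAR-3 and 43 in CAOV-3, up to 5.52 for IFI44L in OVCAR-3, while CXCL11 (6.13), IL6 (2.60) and the NF-kB targets (median 0.61 against 0.05) lay higher in CAOV-3.

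The genes higher in CAOV-3 and OVCAR-3 overlapped. Of 5525 genes above the level minimum in both lines, 60 were counted as higher in CAOV-3, 26 in OVCAR-3 and 22 in both, where independent lists would share 0.282. The 22 were CXCL2, CXCL8, DDX60, HERC5, HERC6, IFI44, IFI44L, IFI6, IFIH1, IFIT1, IFIT3, IFIT5, IRF7, ISG15, LAMP3, MX1, OAS1, OAS3, PARP12, PLSCR1, TRIM14 and TRIM22. Over all genes, which are not independent replicates, the differences of these lines had a Pearson r of 0.298 and a Spearman rho of 0.115. The median difference of CAOV-3 minus OVCAR-3 was 0.57 for NF-kB targets, 0.55 for MHC class I genes and 0.24 for interferon-stimulated genes, each above 10000 random lists of matched level, and -0.47 for G2/M genes, below all of them. Whether the lines differ cannot be tested with 1 array per line and condition.

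SKOV-3 and DOV-13 differed less from their untreated arrays. In SKOV-3, IFI44 was the only gene counted as higher (1.48), with 0 counted when all probe sets of a gene were averaged, and LINC00472 the only one counted as lower (-1.11). The 43 interferon-stimulated genes had a median of 0.12 in this line, at the 99.99th percentile of random lists of matched level, and 33 were higher. Over all genes the differences in SKOV-3 went down with expression level (Spearman rho -0.223). Random lists were matched on mean expression over all arrays, not on the level in SKOV-3, so this trend is not fully taken into account. The untreated median level of interferon-stimulated genes was 6.20 in SKOV-3 and 8.15 in CAOV-3, and that of epithelial markers 6.50 and 9.12. Drug efflux transporters went the other way (6.85 and 4.75). Percentiles in SKOV-3 may therefore be too high for interferon-stimulated genes and epithelial markers. The MHC class I list (0.12, and 0.077 with the mean of all probe sets) lay above all random lists. Ovarian carcinoma and epithelial markers (0.13, 14 of 17 higher, and 0.082 with the mean of all probe sets) and drug efflux transporters (0.21) lay at the 99.96th and 99.86th percentiles, and cholesterol genes (-0.11) and apoptosis inhibitors (-0.10) at the 0.56th and 0.68th. IFIT1 was higher by 0.81 and ISG15 by 0.57, while MX1 (0.003) and CXCL8 (-0.03) hardly differed. In DOV-13, the axon guidance gene SLIT2 (1.15) and CXCL8 (1.13) were counted as higher, and ID2 as lower (-1.54). There the interferon-stimulated genes had a median of 0.06, at the 79.2nd percentile, with 27 of 43 higher, and 0.019 with each array centred on its median. In DOV-13 the lists of cytokines (0.15), NF-kB targets (0.20), MHC class I (0.17) and the stress responses (0.17) lay above all random lists. G2/M genes (0.11), apoptosis inhibitors (0.17) and S phase genes (0.10) lay at the 99.98th, 99.89th and 99.67th percentiles. Centring gave 0.069 for G2/M and 0.059 for S phase genes. NFKBIA was higher by 0.60 and CXCL2 by 0.91 in this line, and IFIT1 differed by -0.01.

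**Figure D3:**
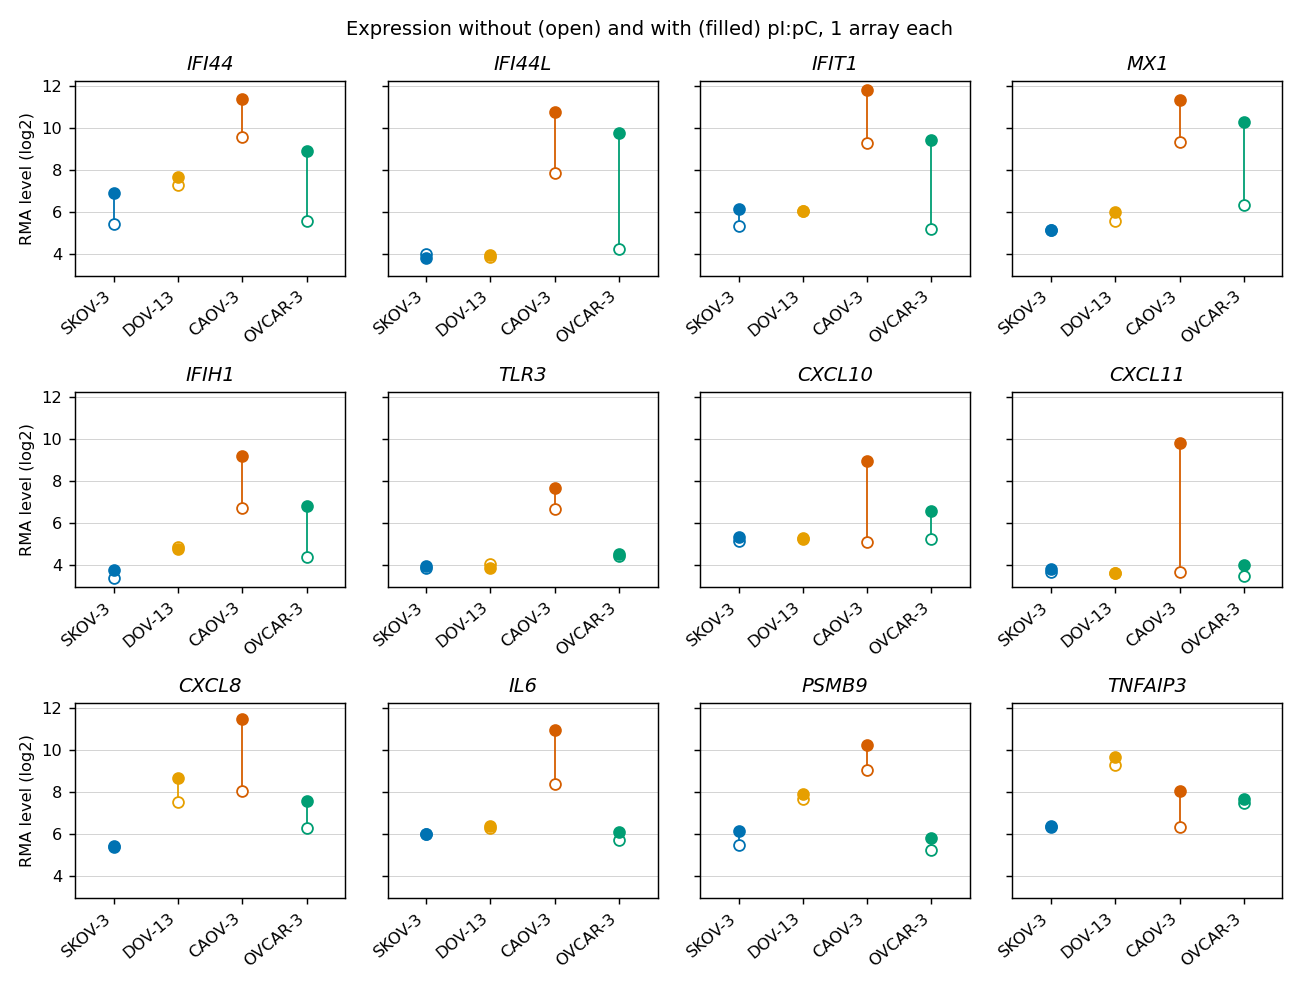
Deposited log2 expression level (vertical axis) of 12 genes in the 4 cell lines (horizontal axis), with open circles for the untreated and filled circles for the treated array, 1 array each. IFI44L, IFIT1 and IFIH1 were higher in treated CAOV-3 and OVCAR-3, CXCL11 and IL6 mainly in CAOV-3, and CXCL8 in every line but SKOV-3.

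Before treatment the lines already differed. Untreated CAOV-3 had the highest level of TLR3 at 6.67, against 4.43 in OVCAR-3, 4.01 in DOV-13 and 3.84 in SKOV-3. IFIH1 was at 6.69 in untreated CAOV-3, 4.82 in DOV-13, 4.35 in OVCAR-3 and 3.37 in SKOV-3, and the adaptor gene MAVS at 6.78, 6.45, 5.02 and 6.98 in the same order. The median level of the 43 interferon-stimulated genes was 8.15 in untreated CAOV-3, 6.85 in DOV-13, 6.25 in OVCAR-3 and 6.20 in SKOV-3. These medians compare the same probe sets between lines.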

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

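The tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the arrays. Among 146 groups of 4 line values tested for 1 value far from the rest, 19 stood out. Chance flags about 1 in 20 independent groups (7.3 of these), but many of the genes were named for a large difference in 1 line and genes are correlated, so that number is no measure here. CAOV-3 was the distant line in 17 of them.

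The first pattern is the large difference of interferon-stimulated genes in treated CAOV-3 and OVCAR-3 and the small one in SKOV-3 and DOV-13. In SKOV-3 the 10 largest differences held 4 interferon-stimulated genes (IFI44, IFIT1, IFITM1 and DDX60, 0.0359 expected, at most 3 in random lists). Random lists hold unrelated genes, while the members of this list are correlated (estimated correlation 0.752). The count therefore cannot decide whether an untreated array stands under the treated label. Of the 43 members 33 were higher and 10 lower in SKOV-3. In DOV-13 the 10 largest held 0, which keeps a wrong label open there too. CXCL5 (1.297, under the level minimum for counting), CXCL8 (1.134), CXCL1 (0.988) and CXCL2 (0.91) were higher in DOV-13. The NF-kB (20 of 23 higher), cytokine and MHC class I lists lay above all random lists, as did the stress response list. These random lists hold unrelated genes too. G2/M (26 of 30) and S phase genes (25 of 28) were also mostly higher in DOV-13, where the median difference of all genes was 0.0342. The lists therefore cannot decide about the label of DOV-13 either. A ceiling shared by the lines is argued against for the list as a whole. Its untreated levels minus those of treated CAOV-3 had a median of -2.724 in DOV-13 (40 of 43 lower) and -3.599 in SKOV-3 (43 of 43 lower). Such a ceiling stays open for the other 3 genes in DOV-13. A limit particular to SKOV-3 or DOV-13 cannot be seen by a comparison with CAOV-3 and stays open. The level of TLR3 before treatment may matter but cannot be told apart from other differences between lines, because untreated OVCAR-3 exceeded DOV-13 by only 0.418. Dose, exposure time and uptake of pI:pC per line stay open and untested.

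The second pattern is the lower G2/M genes in treated CAOV-3, with a median of -0.411, while in DOV-13 the median was 0.112. In OVCAR-3 it was -0.046 (22 of 30 lower, at the 1.19th percentile of random lists). S phase genes in OVCAR-3 had a median of 0.075 (20 of 28 higher, at the 99.97th percentile). The opposite direction of G2/M genes in DOV-13 was not tested, and centring the arrays moved their median to 0.069. A difference in scale between the CAOV-3 arrays that depends on level would shift genes of the same level alike. The medians of random lists of matched level had a mean of -0.0242, and the G2/M list lay -9.99 SD from it. Those random lists hold unrelated genes, while G2/M genes are correlated (estimated correlation 0.853), so the distance in SD overstates the evidence. Fewer cycling cells would lower S phase genes too, and their median in CAOV-3 was 0.262. A shift of cells between phases may underlie it, which stays an untested hypothesis.

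In CAOV-3 the inflammatory genes CXCL11 (6.134), IL6 (2.596) and CCL5 (1.183) stood far above the other lines, as did CTSS (1.604), HLA-F (1.084), FAS (0.883) and TNFRSF10B (0.706). ABCC5 was flagged at a small difference, with 0.142 in CAOV-3 against -0.158 to -0.131 in the other lines. The treated levels of CCL5 (5.81) and CTSS (6.68) in CAOV-3 were under the level minimum for counting (6.758). The median of the double-stranded RNA sensing list (0.437) was also apart there. On the lower side in CAOV-3 were ID4 (-2.112), AGR2 (-1.511), SNAI2 (-1.1), DCLK1 (-0.823), MSMO1 (-0.742), ZMAT3 (-0.62) and ROBO4 (-0.09), and the 16 genes lower by 1 or more exceeded the count of any other line. IFNW1 in SKOV-3 (-0.059) and MVP in DOV-13 (-0.11) lay below the other 3 lines.

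Some values went opposite ways between lines, which was not tested. TGFBI was higher by 0.528 in OVCAR-3 and at -0.817 in DOV-13. IGFBP5 was higher by 0.862 in DOV-13 and at -2.08 in CAOV-3. The apoptosis inhibitors had a median of 0.167 in DOV-13 and -0.105 in SKOV-3, and the drug efflux transporters 0.213 in SKOV-3 and -0.117 in DOV-13. Among 3213 probe sets that name no single gene, 18 were higher by 1 or more in CAOV-3 and 7 in OVCAR-3, 6 of them in both, against 1 in DOV-13 and 0 in SKOV-3.

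The other splits of the 8 arrays that part all 4 pairs are too few for a share under 0.05, with 8 splits and a smallest share of 0.125. For genes the real count was 0 and the highest other 0, so 8 of 8 splits gave as many. For lists the real count was 8 and the highest other 9, and 4 of 8 splits gave as many. The 9 came from turning the labels of SKOV-3 alone, which also gave 1113 genes at an unadjusted p under 0.05 against 448. SKOV-3 differences were correlated with the other lines at -0.168 (DOV-13), -0.067 (CAOV-3) and -0.024 (OVCAR-3) over genes, and went down with expression level (Spearman rho -0.223, against 0.042 to 0.077 in the other lines). Of the 24 splits that part 2 pairs, the pair of splits that part CAOV-3 and OVCAR-3 with treated arrays on 1 side called 28 genes, 23 of them interferon-stimulated. That count points to a structure of the samples, namely that these lines share their large differences.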

How the results depend on the processing

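All settings below were fixed before the data were examined, and the cause of each move was not tested unless stated. Genes raised and lowered over the 4 lines stayed at 0 under every setting run, where the number at an unadjusted p under 0.05 ran from 9 (no replicate block) to 841 (without SKOV-3), and the smallest adjusted p was 0.193 (without SKOV-3). The block changed no gene call over all genes. Without it no interferon-stimulated, MHC class I, cytokine or pro-apoptotic gene passed over its list alone (24, 10, 1 and 1 with it), and the other lists were not run so. Gene lists called, 8 in the main setting, were 0 with an estimated correlation, 0 with fry, 10 with no replicate block and 5 to 9 leaving out a line. The 8 calls were all kept without the block and without SKOV-3, DOV-13 or OVCAR-3, and 4 of them without CAOV-3, where the G2/M list turned direction. The pro-apoptotic BCL2 list was called with the level filter, the mean of probe sets, quantile normalization and without SKOV-3 (adjusted p = 0.00901, 0.0136, 0.048 and 0.0167), and endothelial markers without the block and without CAOV-3 (0.00561 and 0.0277). MHC class II was called without the block (0.0452), and double-stranded RNA sensing was lost with the level filter (0.148).

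Per-line counts fell at a difference of 1.5 by construction: genes raised in SKOV-3 to 0, DOV-13 to 0, CAOV-3 to 55 and OVCAR-3 to 17, and genes lowered in SKOV-3 to 0 and CAOV-3 to 5. With no minimum level 4 genes were lowered in SKOV-3 and 2 in DOV-13. With the mean of all probe sets 0 were raised in SKOV-3 and 10 lowered in CAOV-3, and the medians became 1.56 (interferon-stimulated), 0.288 (cytokines), 0.529 (NF-kB) and 0.794 (MHC class I) in CAOV-3, 0.151 (cytokines) and 0.263 (MHC class I) in OVCAR-3, and for MHC class I 0.077 in SKOV-3 and 0.14 in DOV-13. Centring moved the medians of DOV-13 to 0.019 (interferon-stimulated), 0.11 (cytokines), 0.153 (NF-kB), 0.13 (MHC class I), 0.069 (G2/M) and 0.059 (S phase). Of 128 other list medians recomputed, 22 moved by more than the spread of random lists. Among the 120 named genes none was called under any setting, and none changed sign without the block or with quantile normalization. Leaving out CAOV-3 changed the mean of 62 of these genes by more than 1.5 times or turned its sign, against 20 to 24 for each other line. Many of them were named for large changes in these same data, so this count is no independent measure. Over all genes the SD of the differences was 0.287 in CAOV-3 and 0.159 to 0.204 in the other lines. The mean change turned sign without CAOV-3 for 8 (BNIP3, BIRC5, BIRC2, SLC7A11, HMGCS1, TLR3, IGFBP5 and AGR2), without DOV-13 for 2 (TGFBI and SLIT2), without SKOV-3 for 1 (LINC00472), without OVCAR-3 for 1 (IFNB1) and with the mean of probe sets for 2 (BCL2L1 and BCL2). Signal over background is not given, so which dim genes were measurable is unknown.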

Other observations

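The genes in this part were chosen after their values were seen, and so was the test of the ID probe sets. The test of BMP targets was set after the ID values but before its own result was seen.

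Of the 45 genes counted as higher in CAOV-3 that belong to no fixed list, some were picked by eye, and no enrichment was tested. The complement factor B gene CFB was higher by 2.49, C3 by 1.58, C1S by 1.57, C1R by 1.36 and the complement inhibitor gene CD55 by 1.31. In OVCAR-3 C3 was higher by 0.68 and CFB by 0.53, while C1R (-0.04) and C1S (-0.14) were not. In DOV-13 C3, C1S and CD55 were higher by 0.52, 0.52 and 0.57, and in SKOV-3 these 3 were at -0.11, -0.13 and -0.13. The EGF receptor ligand genes EREG and HBEGF were higher by 1.69 and 1.19 in CAOV-3 and by 0.06 and 0.35 in OVCAR-3. The kallikrein gene KLK10 (2.58), the elastase inhibitor gene PI3 (2.40), the matrix protein gene TNC (2.39) and MYC (1.11) were also higher in CAOV-3.

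Some interferon-stimulated genes were more strongly higher in OVCAR-3 than in CAOV-3. IRF9, part of the interferon-activated transcription complex, was higher by 2.11 in OVCAR-3 and 0.81 in CAOV-3, IFITM1 by 2.99 and 0.75, and IFI27 by 3.20 and 0.99. ISG20 went the other way, with 0.41 and 2.83. RELB, an NF-kB subunit gene, was lower in OVCAR-3 (-0.74) and higher in CAOV-3 (0.97), SKOV-3 (0.64) and DOV-13 (0.35). In DOV-13 the chemokine genes CXCL5 (1.30, under the level minimum for counting) and CXCL1 (0.99) were higher. No test applies to these values.

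The third pattern is the lower expression of the ID genes, which encode inhibitors of helix-loop-helix transcription factors and are targets of BMP signalling. In CAOV-3 ID1, ID2, ID3 and ID4 were at -0.69, -0.78, -1.30 and -2.11, and in DOV-13 ID1, ID2 and ID3 were at -0.79, -1.54 and -0.62 with ID4 at 0.10. The other probe sets of ID4 were at -0.9 and -0.473 in CAOV-3, and at -0.161 and 0.18 in DOV-13. For ID2 and ID4 a single faulty probe set each is argued against by their 3 other probe sets, all lower in CAOV-3 with a median of -0.9. For ID1 and ID3, with 0 other probe sets, it stays open. Lower BMP signalling is a candidate explanation, since 8 other measured BMP targets of 10 had a median of -0.228 in CAOV-3, at the 0.59th percentile of random lists of matched level, with 6 of 8 lower. The same list lay at the 2.59th percentile in DOV-13, the 8.34th in SKOV-3 and the 25.5th in OVCAR-3, so the link remains a hypothesis from 1 array per condition.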
